A study of Homo sapiens with 33 samples.

How the data were processed

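RNA sequencing measured transcript levels in human neutrophils and in peripheral blood mononuclear cells (PBMC, the lymphocytes and monocytes of blood) exposed to drugs in culture. Per the labels, cells of 5 donors were used, neutrophils were collected after 1 h and PBMC after 16 h, and each cell type had 3 groups. These were 1% dimethyl sulfoxide (DMSO, the vehicle control), 100 nM ivermectin (IVM) in 1% DMSO, and 50 µM diethylcarbamazine (DEC). The vehicle of DEC was not given in the sources used here, so a difference between DEC and DMSO may include a difference of vehicle. The labels gave the cell type, the drug and the replicate number of every library, and the 33 libraries fell into 6 groups. There were 15 neutrophil libraries and 18 PBMC libraries, because replicate 1 of each PBMC group had a pair of libraries that the labels call technical replicates. Libraries were made with a strand-specific kit, per the labels.

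The values used were the raw read counts per gene symbol that the authors deposited, in a table for each cell type. Per the submitters' processing notes, TopHat2 2.0.14, HTSeq 0.6.1p1 and the genome build GRCh38.p5 were used. Their settings, the annotation, the strand setting of the counting and the authors' statistical method were not given in the sources used here. Counts of genes that overlap on opposite strands are therefore uncertain. The same holds for near-identical copies, such as FCGR3A and FCGR3B, HBA1 and HBA2, XCL1 and XCL2, the MT1 family, CCL3L1, GOLGA8A, the HLA genes and ribosomal protein genes with pseudogenes. Whole-number values and unequal totals were checked in every column. The neutrophil table held 44088 symbols and that of PBMC held 44089, of which 44088 were shared, and bA395L14.12 was in the PBMC table alone. In all 33 libraries 10010 symbols were listed at 0. Among them were ALOX5 and the ribosomal protein genes RPL7A and RPS25, which cells in general express, so a count of 0 was not read as absent expression. Mitochondrially encoded genes were not analysed here.

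Total counts (rounded) were 10965300 to 17073100 per neutrophil library and 8575140 to 17089400 per PBMC library. At this depth the fit with a block (below) gave a median SE of a log2 fold change of 0.096 in neutrophils and 0.11 in PBMC for genes at 1 CPM (counts scaled to library size) or more. The technical replicate pairs differed by a mean chi-square per gene of 20.6 to 23.0, against 45.6 to 251 between donors of a PBMC group. Sampling of counts alone would give about 1, so the pairs differed by more than sampling. Following the labels, each pair was summed to 1 replicate, so every group had n = 5.

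Genes were tested with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, filterByExpr) in R 4.3.3, separately in each cell type, with the 3 groups sharing 1 estimate of the spread. The Benjamini-Hochberg adjusted p threshold was 0.05 and tests were two-sided. The comparisons were IVM against DMSO, DEC against DMSO, and IVM against DEC. The design named first had group means and no block, and the alternative fixed with it had the replicate number as a block. Because series information states that the replicates were donors whose cells received each exposure, the pairing was checked. Deviations from group means of same-numbered libraries correlated at 0.805 to 0.927 in neutrophils and 0.652 to 0.933 in PBMC, against medians of -0.38 and -0.19 for other numbers. The numbers therefore paired the libraries, and blocked values stand beside those without the block. The biological coefficient of variation was 0.426 without and 0.054 with the block in neutrophils, and 0.392 and 0.113 in PBMC. CPM values printed are TMM-scaled, with mean ± SD over 5 donors, and log2 fold changes are those of the blocked fit unless stated otherwise, with their SE.

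Gene lists were fixed before the data were examined, as were the designs, the rule for named genes and most of the alternatives. They covered inflammatory, lipid mediator, stress and metabolic genes, reported ivermectin targets, and markers of blood cell types. Of 1135 list entries 1122 were matched to a symbol, 13 of them by an older or newer name, and 40 of the 41 lists had enough tested members (at least 5). Lists were tested with camera in limma 3.58.1 (preset inter-gene correlation 0.01) and adjusted over the lists. Camera with an estimated correlation and fry were alternatives. Named genes were, for each drug against DMSO and among genes of at least 1 CPM, up to 10 each way of those past the threshold that had 1 sign in all 5 pairs, first without and then with the block. Where these were fewer than 10, genes with the smallest unadjusted p filled the number to 10 and were given as not past the threshold. For IVM against DEC the same rule took up to 5 each way. For each list that passed, the 4 members with the smallest p were named, together with members called over a list alone. PTGS2, PTGS1, ALOX5, ALOX5AP, ABCB1, P2RX4 and P2RX7 were always named, as textbook targets or carriers of the drugs. A few genes that these rules name are not reported here. The difference of a drug effect between cell types was tested as an interaction over 17441 genes.

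The alternatives were other scalings and filters, DESeq2 1.42.0, limma voom, only the groups compared, single technical replicates, an adjusted p threshold of 0.1, and leaving out each donor and each library. A correction for GC content, a fit on the same genes without it and a fit on libraries whose names end in 1 were added after seeing the data. The GC correction used a lowess trend (span 0.3) of each library on the GC percent of the longest transcript, for the 87.8% and 85.7% of tested genes with a value in GENCODE 29. The edgeR fits with and without the block were tested on simulated data with 200 genes changed in the DEC group. DESeq2, limma voom, the GC correction and the interaction test were not tested in this way. In the blocked fit of DEC against DMSO, the simulation recovered 32%, 78%, 92% and 100% of genes changed 1.2-, 1.5-, 2- and 4-fold among 13120 neutrophil genes. For 16116 PBMC genes the shares were 14%, 52%, 86% and 100%. Without the block they were 0%, 0%, 10% and 68% in neutrophils and 0%, 0%, 34% and 74% in PBMC. The blocked fit also called 9 unchanged genes in neutrophils and 12 in PBMC in that comparison, and 1 and 0 in the comparison without changed genes, while the fit without the block called 0 in each. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 prepared tables and figures.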

Results

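Counts per gene were compared in neutrophils and PBMC of 5 donors after culture with DMSO, IVM or DEC. Ivermectin is a macrocyclic lactone that opens chloride channels of worms, and DEC is a piperazine derivative given against filarial worms that is also known to act on arachidonic acid metabolism of the host. Every group had n = 5, with 10965300 to 17073100 counts per neutrophil library and 8575140 to 17089400 per PBMC library. The 10 most abundant genes took 9.58% to 10.9% of the counts in neutrophils and 6.16% to 9.84% in PBMC. After the low-count filter 13322 genes were tested in neutrophils and 16333 in PBMC. The comparisons addressed which genes each drug changed in each cell type, and which genes differed between the drugs.

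In neutrophils, transcripts of CXCL1, DUSP6 and CDC42EP2 were lower after 1 h with DEC than with DMSO in all 5 donors. CXCL1, a chemokine that attracts neutrophils, had a mean of 70.7 ± 17.6 CPM (SD, n = 5) with DMSO and 53.8 ± 15.3 CPM with DEC. Its log2 fold change in the blocked fit was -0.40 ± 0.053 (SE), with an edgeR adjusted p of 0.000114. DUSP6, a phosphatase that inactivates ERK kinases, fell from 489 ± 224 to 405 ± 198 CPM (log2 fold change -0.29 ± 0.050, adjusted p = 0.0156). CDC42EP2, an effector of the small GTPase CDC42, fell from 24.2 ± 15.2 to 18.4 ± 10.5 CPM (log2 fold change -0.39 ± 0.075, adjusted p = 0.0394). In GENCODE 29 these protein-coding genes lie on chromosome 4 at 73869393 to 73871242 (CXCL1), chromosome 12 at 89347232 to 89353271 (DUSP6) and chromosome 11 at 65314818 to 65322429 (CDC42EP2), and the counts were over whole genes. These were the 3 calls of edgeR with the replicate number as block, with 626 genes at an unadjusted p under 0.05 against 666 expected by chance. With the block limma voom called the same 3 genes, and DESeq2 called CXCL1 and DUSP6. Without the block edgeR called 0 genes (9 at an unadjusted p under 0.05), as did DESeq2 and limma voom. With any donor or library left out, CXCL1 passed in the blocked fit, whereas leaving out the donor of replicate 1, 2 or 3 left it as the 1 call, and the vehicle of DEC was not given in the sources used here.

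**Figure D1:**
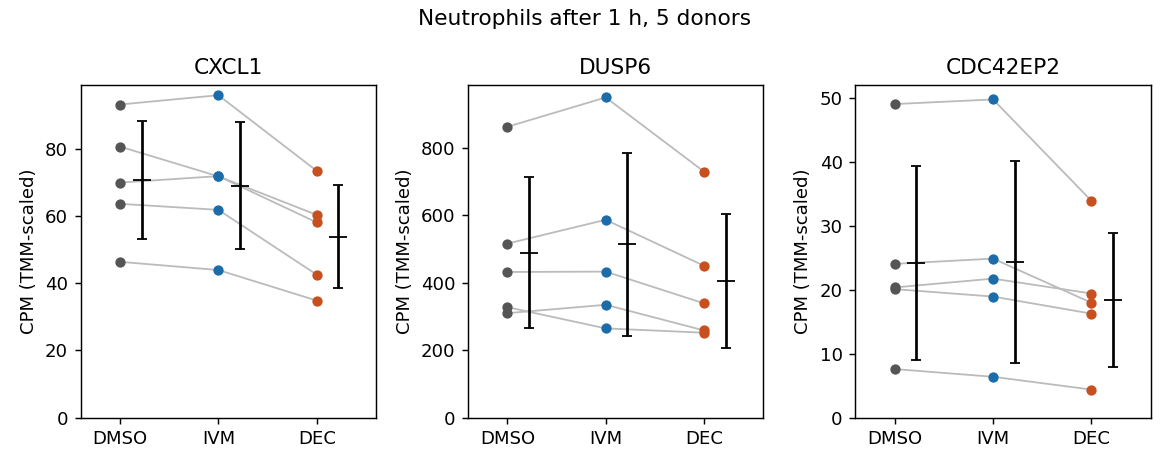
TMM-scaled CPM of CXCL1, DUSP6 and CDC42EP2 in neutrophils after 1 h with DMSO, IVM or DEC. Points are the 5 donors, grey lines join a donor's libraries, and bars are mean ± SD; the DEC value lies below the DMSO value of the same donor in 5 of 5 pairs for each gene.

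Genes next in order for DEC in neutrophils did not pass over all genes. CDCP1, a transmembrane protein phosphorylated by SRC kinases, was at 5.13 ± 3.14 CPM with DEC and 7.43 ± 4.82 CPM with DMSO (log2 fold change -0.53 ± 0.11, adjusted p = 0.103). The log2 fold changes of the stress granule protein gene G3BP1, the polyamine synthesis enzyme gene AMD1 and the transcriptional cofactor gene SERTAD1 were 0.25, 0.23 and 0.26 (adjusted p = 0.210, 0.227 and 0.227), positive in 5 of 5 pairs. For the Fc receptor gene FCGR3A, whose reads may be split with its near-identical copy, MCEMP1 and KIAA0226L they were -0.31, -0.21 and -0.18, negative in 5 of 5 pairs (adjusted p = 0.227, 0.341 and 0.398). The cyclooxygenase genes PTGS1 and PTGS2 had log2 fold changes of 0.15 ± 0.071 and -0.09 ± 0.069, and ALOX5AP, which activates arachidonate lipoxygenase, of -0.02 ± 0.045 (adjusted p = 1.00 each). ALOX5 was listed at 0 in all 33 libraries.

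Of the 40 gene lists, 9 were lower with DEC in neutrophils in the blocked camera test and 0 were higher. With an estimated correlation none of the 9 passed (adjusted p = 0.228 to 0.688 with an estimated correlation), and leaving out a donor gave 2 to 10 lists, 2 without the donor of replicate 1. All 9 tested chemokine genes had negative log2 fold changes, with a median of -0.18 (adjusted p = 1.57e-05, or adjusted p = 0.228 with an estimated correlation). Fry with the block also called this list as falling on balance (adjusted p = 0.0400). Adjusted over the list alone, CXCL1 and CXCL8 passed, CXCL8 with a log2 fold change of -0.23 ± 0.066 (adjusted p = 0.578 over all genes). CXCL8 was higher with DEC in 1 of 5 pairs. CXCL16 was at -0.10 and CXCL3 at -0.34, lower in 5 of 5 pairs each. Of 34 immediate early genes, 25 were negative (adjusted p = 0.0297, median -0.03), and adjusted over the list alone DUSP6 and the kinase gene SGK1 (log2 fold change -0.15) passed, beside NR4A3 at -0.18. Chemokine receptor genes (12 of 16 negative, adjusted p = 0.0196) included CXCR4 and CXCR1, both at -0.16, which passed adjusted over the list alone, and CCR1 and CXCR5 at -0.13 and -0.27. T cell activation genes (20 of 21 negative, adjusted p = 0.00171) had no such call, and NR4A1, IRF4, TIGIT and FASLG were at -0.21, -0.23, -0.96 and -0.66. Fc and complement receptor genes were negative in 18 of 24 (adjusted p = 0.0297), with FCGR3A called adjusted over the list alone and CD93, C5AR2 and C5AR1 at -0.12, -0.11 and -0.10. Neutrophil markers were negative in 19 of 22 (adjusted p = 0.0195), with VNN3 (-0.19) and CXCR1 called adjusted over the list alone and KCNJ15 and CEACAM3 at -0.08 and -0.09. Ribosomal protein genes were negative in 61 of 70 (adjusted p = 0.00601), for example RPS21, RPL29, RPS4X and RPL10A at -0.18, -0.15, -0.12 and -0.11. B cell markers were negative in 10 of 13 (adjusted p = 0.0297), with IGKC, PAX5, CD79B and CD22 at -0.18, -0.37, -0.45 and -0.18, and monocyte markers in 15 of 21 (adjusted p = 0.0483), with TNFRSF8, HMOX1, CD14 and CD68 at -0.20, -0.12, -0.11 and -0.11. PAX5 and CD79B were at means of 3.42 and 1.39 CPM in neutrophils. Of markers at least 10 times higher in PBMC, 20 of T cells had a mean of 8.19 CPM in these libraries and 8 of B cells 2.73 CPM. Which cells the transcripts of the T cell activation and B cell lists came from was not tested. Immediate early genes and Fc and complement receptors passed among genes with a GC value before the GC correction, both added after seeing the data (adjusted p = 0.0387 each), and not after it (0.0872 and 0.0582), and the heat shock list passed as higher (adjusted p = 0.0498, or adjusted p = 0.489 with an estimated correlation). Without the block 3 lists passed, namely chemokines, T cell activation genes and B cell markers (adjusted p = 0.0387, 0.0233 and 0.0455, or adjusted p = 0.938 with an estimated correlation).

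Markers of mononuclear cells were also slightly lower with DEC in the same neutrophil libraries. The mean log2 fold change of 36 markers of T, B and NK cells and monocytes that were at least 10 times higher in PBMC was -0.079 ± 0.012 (SE over 5 donors), and 3 monocyte markers among them were at -0.20 ± 0.15. The monocyte mean rested mostly on STAB1 (-0.57 at 2.41 CPM), while VCAN and CSF1R were at -0.06 and 0.03. Further members passed adjusted over the list alone, though their lists did not pass: ABCC2 (-0.47), TRAF1 (-0.19), the erythroid genes SLC4A1 (-0.65) and HBA2 (-0.31), and TIPARP, a target of the aryl hydrocarbon receptor (0.22). Together with the genes above, 15 such calls fell in 10 lists, with VNN3 and CXCR1 counted more than once, and without the block there were 0. These calls were not adjusted across the 40 lists, and chance alone can give some of them.

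In neutrophils no single gene passed between IVM and DMSO. edgeR called 0 of 13322 genes without and with the block, with 9 and 470 genes at an unadjusted p under 0.05 (666 expected by chance), and DESeq2 and limma voom also called 0. CXCL1, DUSP6 and CDC42EP2 had log2 fold changes of -0.04, 0.03 and -0.0043 with IVM. The smallest p values belonged to HGSNAT, a lysosomal enzyme gene (log2 fold change -0.24), ARID3A (0.18), PARVB (0.68), the nuclear receptor gene NR4A3 (-0.22) and CREM, a cAMP-responsive transcription factor gene (-0.21), all at an adjusted p of 1.00. RCSD1 (0.17), SERPINE2 (0.83), CYP27A1 (0.20), FRMD4B (-0.21) and GPD2 (-0.28) followed. Levels of the drug efflux pump gene ABCB1, which exports ivermectin, were 3.49 ± 1.28 CPM with IVM and 3.65 ± 1.35 CPM with DMSO, and P2RX4, a channel that ivermectin potentiates, stood at 24.7 ± 9.74 and 25.2 ± 11.4 CPM. P2RX7, PTGS1, PTGS2 and ALOX5AP had log2 fold changes of -0.15, 0.04, -0.09 and -0.03. The 95% interval of the blocked fit excluded a 2-fold change in 99.5% of the 11913 genes at 1 CPM or more, and a 1.5-fold change in 88.1%.

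Immediate early genes and ribosomal protein genes were lower as lists with IVM in neutrophils in the blocked camera test, and the other 38 lists did not pass. Both had adjusted p = 0.915 with an estimated correlation, and without the block 0 lists passed. Of the immediate early genes 26 of 34 were negative (median -0.06, adjusted p = 0.0176), with NR4A3, NR4A2 (-0.16), FOSL2 (-0.12) and FOSB (-0.16) first in order and no call adjusted over the list alone. Of the ribosomal protein genes 55 of 70 were negative (median -0.05, adjusted p = 0.00310), among them RPL24 (-0.11), RPL17 (-0.37) and RPL39 (-0.10). OXER1, a receptor for oxidised arachidonate, had a log2 fold change of 0.27 and passed adjusted over the list alone, the 1 such call of this comparison. Without an adjustment across the 40 lists, chance alone can give 1 such call.

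Between the drugs, neutrophils had 3 genes higher and 5 lower with IVM than with DEC, each in 5 of 5 pairs. CXCL1 (69.0 ± 18.8 against 53.8 ± 15.3 CPM), DUSP6 (513 ± 272 against 405 ± 198) and CDC42EP2 (24.3 ± 15.8 against 18.4 ± 10.5) were higher with IVM, with log2 fold changes of 0.36 ± 0.053, 0.32 ± 0.050 and 0.39 ± 0.075 (edgeR adjusted p = 0.000940, 0.00261 and 0.0213). SERTAD1 (-0.32, adjusted p = 0.0213), G3BP1 (-0.31, 0.0145), CYB5D1 (-0.29, 0.0213), AMD1 (-0.27, 0.0213) and PCF11, a factor for cleavage and termination of transcripts (-0.22, 0.0288), were lower. SERTAD1 lies on chromosome 19 at 40421592 to 40426025, G3BP1 on 5 at 151771045 to 151812785, CYB5D1 on 17 at 7857746 to 7862282, AMD1 on 6 at 110874770 to 110895713 and PCF11 on 11 at 83156988 to 83187451. These 8 calls came from the blocked fit (795 genes at an unadjusted p under 0.05), in which DESeq2 called 17 genes and limma voom 9. Without the block edgeR, DESeq2 and voom called 0, with 14 genes at an unadjusted p under 0.05 in edgeR. Without the donor of replicate 1 the blocked count was 0.

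**Figure D2:**
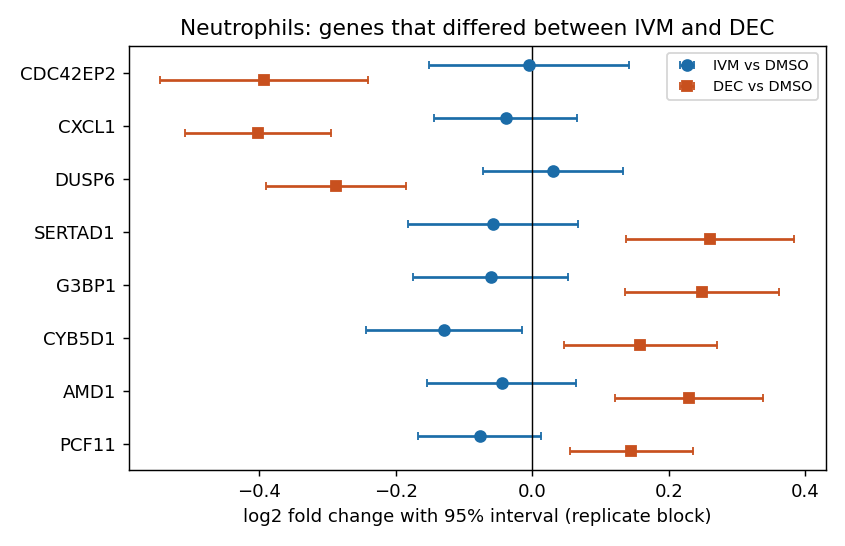
Log2 fold changes against DMSO, with 95% intervals from the blocked edgeR fit (n = 5), of the 8 genes that differed between IVM and DEC in neutrophils. Circles are IVM and squares DEC; for CXCL1 the IVM estimate is -0.04 and the DEC estimate -0.40.

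The chemokine list was higher with IVM than with DEC in neutrophils (7 of 9 positive, median 0.13, camera adjusted p = 0.0259, or adjusted p = 0.513 with an estimated correlation), and the other 39 lists did not pass in the blocked fit. Among genes with a GC value alone, added after seeing the data, 6 lists passed, and with the GC correction 1, in each case 0 with an estimated correlation (the 6 at adjusted p = 0.534 to 0.877 with an estimated correlation). Adjusted over the list alone, CXCL1, CXCL3 (log2 fold change 0.51) and CXCL8 (0.18) passed, and CCL3L1, a gene with near-identical copies, was at 0.14. The lipid mediator receptor genes OXER1 (0.31), PTGER4 (0.15) and LTB4R (0.16) passed in the same way, as did MYC (0.70), SGK1 (0.15), TRAF1 (0.19), CXCR4 (0.16), CXCR1 (0.15), CD3G (0.69), IGKC (0.20), OLIG2 (0.43) and, lower with IVM, TIPARP (-0.28). CD3G was at a mean of 2.19 CPM in neutrophils. In all there were 17 such calls in 10 lists, with MYC counted more than once, and 0 without the block. They were not adjusted across the 40 lists, and chance alone can give some of them. PTGS1, PTGS2, ALOX5AP, ABCB1, P2RX4 and P2RX7 had log2 fold changes between -0.12 (P2RX7) and 0.01 (P2RX4). Of the genes at 1 CPM or more, 99.4% had an interval that excluded a 2-fold difference between the drugs.

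In PBMC, 15 of the 40 gene lists were higher after 16 h with IVM than with DMSO in the blocked camera test and 0 were lower, while no single gene passed. None of the 15 passed in camera with an estimated correlation (adjusted p = 0.464 to 0.569 with an estimated correlation), and fry with the block called 0. All 21 tested chemokine genes had positive log2 fold changes, with a median of 0.33 (adjusted p = 7.32e-05). Among them CCL22 was at 124 ± 98.8 CPM with IVM and 72.7 ± 39.7 CPM with DMSO (log2 fold change 0.62 ± 0.26), and CCL1, CCL19 and XCL2 had log2 fold changes of 0.65, 0.90 and 0.57. Of the NF-kB targets and inflammatory cytokines 28 of 34 were positive (adjusted p = 6.29e-05), and the adhesion molecule gene ICAM1 (0.32), the protease inhibitor gene SERPINB2 (0.78) and the macrophage growth factor gene CSF1 (0.66) passed adjusted over the list alone, beside IL1B at 0.63. Ribosomal protein genes were positive in 70 of 70 (median 0.15, adjusted p = 1.41e-11), for example RPL35 (0.21), RPL29 (0.21), RPS2 (0.23) and RPLP2 (0.22), and nuclear respiratory chain genes in 41 of 46 (adjusted p = 0.000119), for example UQCRQ (0.27), UQCRFS1 (0.22), COX6A1 (0.19) and SDHA (0.18). T cell activation genes were positive in 25 of 26 (adjusted p = 0.000119), with GZMB at 0.42, TBX21 at 0.35, BATF at 0.33 and LAG3 at 0.35. Genes induced by interferon gamma and of antigen presentation were positive in 27 of 30 (adjusted p = 0.000105), where SOCS1, a feedback inhibitor of cytokine signalling (0.60), and HLA-DPB1 (0.59) passed adjusted over the list alone, beside TAP2 (0.30) and HLA-DRA (0.41). Without the block 9 lists passed (1 without the donor of replicate 3), and with it 5 of 16 exchanges of labels within donors gave at least 15 lists, the real labels included.

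The other 9 of these 15 lists likewise did not pass in that alternative (adjusted p = 0.464 to 0.569 with an estimated correlation). Immediate early genes were positive in 27 of 34 (adjusted p = 0.000259), with DUSP5 (0.25), DUSP4 (0.39), IER2 (0.23) and PPP1R15A (0.20) first in order. Apoptosis regulators were positive in 27 of 35 (adjusted p = 0.000105), where BCL2L1, which encodes the anti-apoptotic BCL-XL, passed adjusted over the list alone (0.41) and CDKN1A and BCL2A1 were at 0.31 and 0.30. Metallothioneins and zinc handling genes were positive in 10 of 13 (adjusted p = 0.0367), where MT2A (0.46) passed adjusted over the list alone. MT1E, MT1G and MT1M were at 0.62, 1.03 and 0.88, where MT1M was at 2.43 in 1 donor and -0.18 to 0.16 in the others, and MT1G went from 1.68 to 0.25 without that donor in the fit without the block. Adhesion and migration genes (29 of 37, adjusted p = 0.00209) held ICAM1 and ADGRE5 (0.26) as calls adjusted over the list alone, besides ICAM3 (0.28) and ITGAM (0.23). Genes of the unfolded protein and integrated stress response were positive in 22 of 29 (adjusted p = 0.00578), among them TRIB3 (0.43), PSAT1 (0.37) and PDIA4 (0.20). Cholesterol synthesis genes were positive in 19 of 25 (adjusted p = 0.0185), with PMVK at 0.31, EBP at 0.22 and STARD4 at -0.19. Fc and complement receptors (20 of 26, adjusted p = 0.0127) held FCAR (0.62), CD93 (0.60) and FCGR2B (0.26), and the heat shock list (19 of 24, adjusted p = 0.0367) FKBP4 (0.19), DNAJB1 (0.17), HSPA8 (0.22) and DNAJB4 (-0.22). Erythroid markers were also higher (15 of 17, adjusted p = 0.00587), with HBA1, HBA2, GATA1 and AHSP at 0.32, 0.28, 0.41 and 0.36. The NK cell marker list did not pass (adjusted p = 0.0813), but GZMB, PRF1 (0.38) and XCL2 passed adjusted over the list alone. The mean log2 fold change of 21 monocyte markers in the same libraries was -0.075 ± 0.20 (SE over 5 donors). In all, 12 calls adjusted over the list alone fell in 6 lists, with ICAM1 counted more than once. Such calls were not adjusted across the 40 lists, and chance alone can give some of them.

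**Figure D3:**
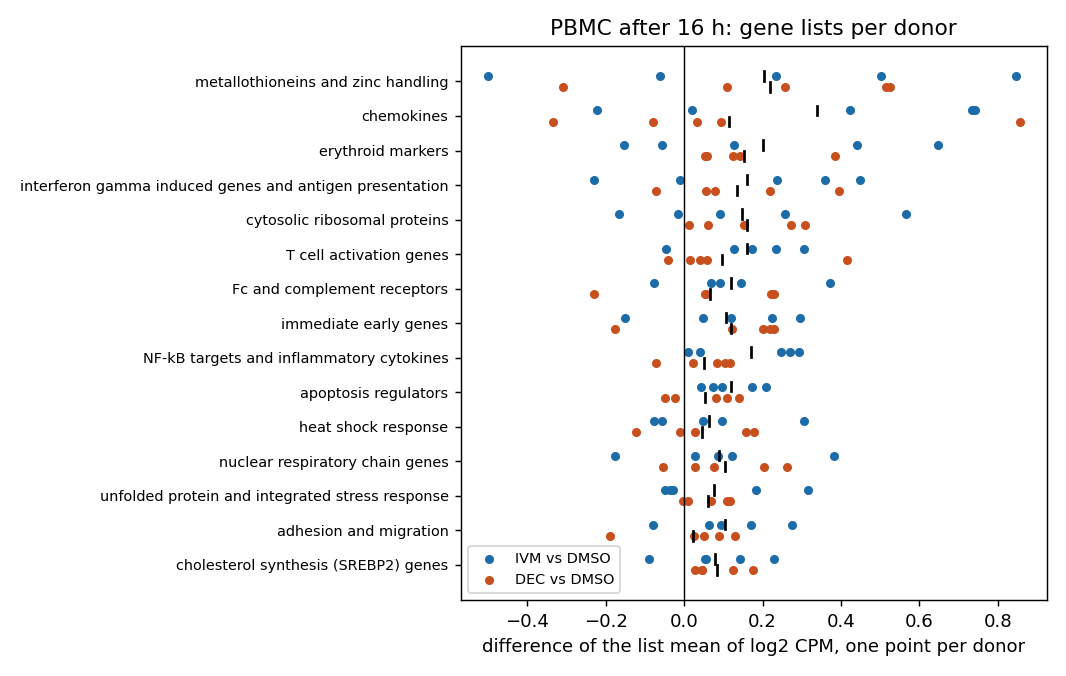
Difference from DMSO of the mean log2 CPM of each of the 15 lists higher with IVM in PBMC, with 1 point per donor for IVM (blue) and DEC (orange) and a black tick at the mean of the 5 donors. Donors spread on both sides of 0 for most lists, while all 5 IVM points of the NF-kB and apoptosis lists lie above 0.

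The single genes with the smallest p for IVM in PBMC were GGH, a folate hydrolase gene (6.04 ± 4.97 CPM with IVM and 9.70 ± 8.60 CPM with DMSO, log2 fold change -0.62 ± 0.12), BCL2L1 (0.41), the kinase gene PIM1 (0.30), SOCS1 (0.60), EHD1 (0.36), FLJ32255 (0.38), the cytokine gene IL36G (0.64), ADAM19 (0.30), AASS (-0.39) and GOLGA8A (-0.55). Each had 1 sign in 5 of 5 pairs and an edgeR adjusted p of 0.597 with the block. edgeR called 0 of 16333 genes without and with the block, with 35 and 1360 at an unadjusted p under 0.05 against 817 expected by chance. With the block DESeq2 called PIM1 alone and limma voom called 0. ALOX5AP was at 285 ± 413 CPM with IVM and 172 ± 225 CPM with DMSO (log2 fold change 0.47 ± 0.15, adjusted p = 0.597), and PTGS1, PTGS2, ABCB1, P2RX4 and P2RX7 were at 0.11, 0.07, 0.11, 0.10 and 0.03. The 95% interval excluded a 2-fold change in 97.6% of 15112 genes at 1 CPM or more and a 1.5-fold change in 79.8%.

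With DEC, PBMC had 4 lists that were higher than with DMSO in the blocked camera test and 0 that were lower, and no single gene passed. All 4 had adjusted p = 0.922 with an estimated correlation. Ribosomal protein genes were positive in 69 of 70 (median 0.16, adjusted p = 2.94e-09), for example RPS15, RPS28 and RPL18 at 0.29, 0.32 and 0.26. Nuclear respiratory chain genes were positive in 38 of 46 (adjusted p = 0.00200), with NDUFS7, COX8A, ATP5D and ATP5G1 at 0.29, 0.30, 0.29 and 0.27. Immediate early genes were positive in 25 of 34 (adjusted p = 0.0130), with KLF2 (0.26), DUSP2 (0.30), NR4A1 (0.35) and JUND (0.26), and genes induced by interferon gamma and of antigen presentation in 28 of 30 (adjusted p = 0.0161), with HLA-DPB1 (0.52), SOCS1 (0.38) and HLA-DRA (0.43). The GC correction, added after seeing the data, left the other 3 past the threshold and not the immediate early genes (adjusted p = 0.151, and 0.0212 on the same genes before it). Without the block the ribosomal and respiratory chain lists passed (adjusted p = 0.000166 and 0.00891, or adjusted p = 0.953 with an estimated correlation). MT2A (0.52), HBA1 (0.51), the small heat shock protein gene HSPB1 (0.39) and the HSP90 cochaperone gene CHORDC1 (-0.27) passed adjusted over the list alone, 4 calls in 3 lists. These calls were not adjusted across the 40 lists, and chance alone can give calls in a few lists.

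No gene passed over all genes for DEC in PBMC. LIPE, the hormone-sensitive lipase gene, was at 11.4 ± 1.64 CPM with DEC and 8.02 ± 1.86 CPM with DMSO (log2 fold change 0.52 ± 0.11), and BLOC1S3 was at 0.32. The palmitoyltransferase gene ZDHHC20 was at 131 ± 23.6 and 168 ± 19.0 CPM (-0.37 ± 0.081), and CHIC1, TMX3, the T cell transcription factor gene IKZF2, DNAJB14, GABPA, RTKN2 and G2E3 were at -0.43, -0.33, -0.35, -0.43, -0.36, -0.40 and -0.38. Each had 1 sign in 5 of 5 pairs and an edgeR adjusted p of 0.337 with the block. edgeR called 0 of 16333 genes without and with the block (57 and 2082 at an unadjusted p under 0.05, 817 expected by chance), and DESeq2 and limma voom called 0. P2RX4 was at 75.2 ± 32.9 CPM with DEC and 63.3 ± 26.5 CPM with DMSO (log2 fold change 0.23 ± 0.085, adjusted p = 0.337), and PTGS1, PTGS2, ALOX5AP, ABCB1 and P2RX7 were at 0.11, -0.20, 0.17, -0.07 and 0.15. Log2 fold changes of this comparison rose with the GC content of the gene (Spearman 0.71 across genes at 1 CPM or more with a GC value, which are not independent replicates). The 95% interval excluded a 2-fold change in 98.1% of 15112 genes.

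Between IVM and DEC in PBMC, 5 lists were higher with IVM and 1 was lower in the blocked camera test, and no single gene passed. The 5 higher lists had adjusted p = 0.759 to 0.905 with an estimated correlation, and without the block 0 lists passed. The interferon-stimulated genes were lower with IVM (38 of 41 negative, median -0.19, adjusted p = 0.00470, or adjusted p = 0.987 with an estimated correlation), with the macrophage lectin gene SIGLEC1 at 19.6 ± 24.5 and 48.9 ± 48.9 CPM (log2 fold change -1.06 ± 0.43) and XAF1, MX2 and IRF7 at -0.27, -0.30 and -0.26. Chemokines were higher (18 of 21 positive, median 0.20, adjusted p = 0.00140), where CCL1 (0.79) passed adjusted over the list alone and CXCL5, CXCL8 and CCL20 were at 1.08, 0.45 and 0.42. NF-kB targets and inflammatory cytokines were higher (26 of 34, adjusted p = 0.00583), where SERPINB2 passed adjusted over the list alone, at 441 ± 206 CPM with IVM and 241 ± 141 CPM with DEC (1.01 ± 0.22), beside IL1B (0.56), IL1A (0.64) and CSF2 (0.58). Adhesion genes (27 of 37, adjusted p = 0.00231) held ITGA1 (0.47) as such a call, besides ITGA4 (0.22), ITGB3 (0.66) and VNN3 (0.45). Apoptosis regulators (30 of 35, adjusted p = 0.00231) held FAS (0.19), BCL2A1 (0.19), BCL2L1 (0.16) and FASLG (0.33), and pattern recognition receptors (22 of 34, adjusted p = 0.0497) TLR10 (0.33), TLR6 (0.20), TLR4 (0.23) and CLEC5A (0.35). The low-affinity IgE receptor gene FCER2 (0.75) was the last of 4 calls adjusted over the list alone, in 4 of 40 lists. They were not adjusted across lists, and chance alone can give calls in a few lists. Among genes with a GC value alone, added after seeing the data, pattern recognition receptors did not pass and monocyte markers were lower with IVM, before a GC correction (adjusted p = 0.0826 and 0.0300) as after it (0.204 and 0.0247). For the monocyte markers adjusted p = 0.952 with an estimated correlation before it and 0.898 after it. edgeR called 0 genes without and with the block (40 and 438 at an unadjusted p under 0.05, 817 expected by chance), and DESeq2 and limma voom called 0. PTGS1, PTGS2, ALOX5AP, ABCB1, P2RX4 and P2RX7 had log2 fold changes between -0.13 (P2RX4) and 0.31 (ALOX5AP), and 97.7% of genes had an interval that excluded a 2-fold difference.

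A drug effect was not shown to differ between the cell types for any gene. The interaction test in edgeR called 0 of 17441 genes for IVM and for DEC, without the block (93 and 99 at an unadjusted p under 0.05) and with it (915 and 1689), and limma voom called 0. The interaction adjusted p with the block was 0.470 for CXCL1, DUSP6 and CDC42EP2 with DEC, whose log2 differences of PBMC minus neutrophils were 0.53, 0.32 and 0.71. Incubation times differed between the cell types, so the test compared 16 h with 1 h as well.

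Log2 fold changes of IVM and DEC against the shared DMSO libraries correlated across genes at r = 0.45 in neutrophils and 0.61 in PBMC, genes not being independent replicates. Simulated unchanged groups against the same controls gave 0.497 and 0.487, and covariances of 0.00920 and 0.0121 against the observed 0.00790 and 0.0190. With the control donors split between the drugs, the median r was -0.03 in neutrophils (-0.09 to 0.07) and 0.10 in PBMC (-0.18 to 0.26). In PBMC 289 genes were at an unadjusted p under 0.05 and higher with both drugs (35.8 for independent lists) and 362 were lower with both (51.3), and in neutrophils the numbers were 25 (3.74) and 54 (7.64). Shared controls raise these numbers without any effect: simulated unchanged groups gave a mean of 86.6 and 73.0 in PBMC (30 simulations, 76 to 102 and 55 to 90) and 65.5 and 60.6 in neutrophils (46 to 83 and 51 to 71), where the observed 25 lay below the lowest simulated value. Part of the excess in PBMC may come from the shared controls. The simulation drew each gene independently and held no GC trend between libraries. Its ranges therefore cannot decide whether the observed r and overlaps exceed what unchanged groups give. In PBMC the log2 fold changes of both drugs rose with GC content (Spearman 0.45 for IVM and 0.71 for DEC).

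The other 19 lists passed in no comparison, without or with the block, and their smallest adjusted p was 0.0506. With the GC correction, added after seeing the data, 3 of them passed in PBMC: glycolysis and hypoxia genes, lower with IVM and DEC (adjusted p = 0.0371 and 0.0124), NRF2 targets, lower with IVM (0.0292), and NK cell markers, higher with IVM (0.0371). None did so with an estimated correlation (adjusted p = 0.586 to 0.812 with an estimated correlation). Among genes with a GC value before the correction, eicosanoid receptors (higher) and replication-dependent histone genes (lower) passed between IVM and DEC in neutrophils (adjusted p = 0.0476 each, or adjusted p = 0.534 with an estimated correlation). In the blocked fits the medians of eicosanoid synthesis enzymes, the pathway on which DEC is known to act, lay between -0.05 and 0.08 (smallest adjusted p = 0.294), and those of eicosanoid receptors between -0.12 and 0.15 (0.0506). ALOX5 was listed at 0 in all 33 libraries, so the enzyme medians do not cover it. The same holds below for PRTN3 and AZU1 in the granule list and GSDMD in the extracellular trap list. Medians of the reported ivermectin targets and transporters lay between -0.05 and 0.03 (smallest adjusted p = 0.338). For innate functions the medians were -0.03 to 0.12 for NADPH oxidase genes (0.0601), -0.07 to 0.09 for neutrophil granule proteins (0.175), -0.01 to 0.04 for extracellular trap genes (0.458) and -0.04 to 0.12 for type 2 cytokines with their receptors and targets (0.0727). For metabolic and growth genes they were -0.04 to 0.02 for LXR targets (0.414), -0.04 to -0.0011 for glycolysis and hypoxia genes (0.186), -0.06 to 0.05 for NRF2 targets (0.199), -0.05 to 0.05 for the xenobiotic response (0.264), -0.06 to 0.02 for proliferation genes (0.302) and -0.08 to 0.06 for replication-dependent histone genes (0.0506). For cell type markers they were -0.08 to 0.07 for T cells (0.145), -0.10 to 0.15 for NK cells (0.0813), -0.06 to 0.18 for basophils (0.256), -0.14 to 0.12 for eosinophils (0.124), -0.05 to 0.13 for dendritic cells (0.110) and -0.13 to 0.04 for platelets (0.338).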

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

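The tests of technical explanations, the splits and the exchanges of labels in this part were chosen only after the results were seen, and the GC correction and the fit on libraries ending in 1 were added then, while the interaction tests were planned.

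In 21 of 255 groups of 5 values, 1 donor stood apart from the others by Dixon's criterion, and chance gives this in about 1 in 20 groups. Among CPM values in neutrophils these were PTGS2 with DEC (539.6 against 153 to 219 in the others), ALOX5AP with IVM (1455 against 1086 to 1172), P2RX7 with IVM (4.53 against 0.900 to 1.82), and AMD1 (123.3 against 92.7 to 98.0) and PCF11 (340.1 against 209 to 241) with DMSO. CYB5D1 stood apart in all 3 neutrophil groups in the donor of replicate 3, at 118 CPM with DMSO, 113 with IVM and 153 with DEC, against 39.2 to 65.6 in the other donors. ALOX5AP in PBMC stood apart in the donor of replicate 5, at 571 CPM with DMSO, 1015 with IVM and 524 with DEC, against 40.6 to 204.6 in the others. Among log2 differences within a donor, FOSB with IVM in neutrophils was -0.74 in 1 donor (others -0.12 to 0.02). With DEC in neutrophils HMOX1 was -0.27 (others -0.11 to -0.06) and CD68 -0.24 (others -0.11 to -0.05), both in the donor of replicate 4. With IVM in PBMC 1 donor stood at 1.81 for CSF1 (others 0.27 to 0.54), 2.43 for MT1M (others -0.18 to 0.16), 0.70 for UQCRQ (others 0.11 to 0.22), 0.82 for BCL2A1 (others 0.07 to 0.28), -0.24 for PRF1 (others 0.39 to 0.63) and -0.38 for GATA1 (others 0.36 to 0.65). With DEC in PBMC 1 donor stood at 1.04 for SOCS1 (others -0.03 to 0.22).

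For 4 results the log2 fold change had 1 sign in all 5 donors of a cell type and the other sign in all 5 of the other. UQCRQ with IVM was at 0.27 in PBMC and -0.17 in neutrophils, and the interaction test with the block gave a difference of 0.44 and an adjusted p of 0.912. With DEC the values in PBMC and neutrophils were 0.31 and -0.39 for CDC42EP2, -0.12 and 0.23 for AMD1, and 0.21 and -0.45 for CD79B, with an interaction adjusted p of 0.470 each. None of these differences was therefore past the threshold. CD79B, a B cell marker, was at a mean of 1.39 CPM in neutrophils, so its value there rests on few counts.

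The fall of CXCL1, DUSP6 and CDC42EP2 with DEC in neutrophils was weighed against a GC trend, a smaller share of mononuclear cells, and a vehicle that differs between DEC and the other groups. With the GC correction 3 of the 3 genes passed, at log2 fold changes of -0.39, -0.27 and -0.41, which argues against a GC trend as the whole cause. Mononuclear cell markers had a mean log2 fold change of -0.079 ± 0.012, smaller than the smallest fall of the 3 genes (-0.29), which argues against a smaller share of mononuclear cells as the whole cause. The 3 monocyte markers (-0.20 ± 0.15) cannot decide on a loss of monocytes. Their mean rested mostly on STAB1 (-0.57 at 2.41 CPM), while VCAN and CSF1R were at -0.06 and 0.03. A different vehicle stays open, because 3 of the 3 genes also passed between IVM and DEC and the vehicle of DEC was not given in the sources used here. An effect of DEC itself is a hypothesis that cannot be told apart from the vehicle with these groups.

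The excess of low p values for DEC in PBMC (2082 genes at an unadjusted p under 0.05 against 817 by chance) was weighed against a GC trend and against a control library of another preparation, since the name of the DMSO library of replicate 2 ends in 2 where those of its partners end in 1. Among genes with a GC value the number was 2010 before the GC correction and 429 after it, against 700 by chance. A GC trend between libraries may therefore account for the excess, and a drug effect that itself follows GC content stays open. Without the donor of replicate 2 the number was 1292 against 816 by chance, above 1.5 times as many, and 1390 to 2333 without any other donor. With libraries ending in 1 alone and without that donor it was 1200 against 817, under 1.5 times as many, and exchanged labels gave up to 1325 with all donors, so the control library is not excluded as a part of the cause.

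The higher gene lists with IVM in PBMC were weighed against a GC trend, members that move together between libraries of a donor, and a larger share of monocytes. With the GC correction 19 lists passed, 17 higher, including the 15, and 2 lower (NRF2 targets and glycolysis), against 13 higher on the same genes before it, which argues against a GC trend as the cause, though none passed with an estimated correlation (adjusted p = 0.409 or more with an estimated correlation). Of the 16 exchanges of labels within donors, 5 gave at least the 15 lists of the real labels, the real one included, and the highest other gave 21, so members that move together between libraries of a donor are a candidate explanation. Monocyte markers had a mean log2 fold change of -0.075 ± 0.20, higher in 2 of 5 donors, against a median of 0.126 for the lists that passed, so the spread between donors leaves a larger share of monocytes open. An effect of IVM on these lists stays open as well.

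Chance was examined by regrouping the libraries. Without the block edgeR called 0 genes in each of the 6 comparisons, which 33 of the 33 drawn splits reach by construction (highest other 1, in PBMC between IVM and DEC), so a count of 0 says nothing about chance here or below. These splits move libraries across donors and ignore the pairing, so donor differences widen them. For lists in neutrophils the real counts for IVM, DEC and IVM against DEC were 0, 3 and 0, reached by 33, 27 and 33 of 33 splits (highest other 14, 13 and 18). In PBMC the counts 9, 2 and 0 were reached by 25, 31 and 33 of 33 splits (highest other 29, 27 and 25), and no list count without the block stood apart from regrouped libraries. With the block, labels can be exchanged within 5 donors in 16 ways that part every pair, too few for a share under 0.05. The real neutrophil counts of 0, 3 and 8 genes stood beside a highest other of 3, 1 and 3, with 16, 1 and 1 of the 16 exchanges at least as large, and the PBMC counts of 0, 0 and 0 beside 24, 0 and 0, with 16 of 16 each. For lists the exchanges gave at least the real counts of 2, 9 and 1 in neutrophils in 8, 1 and 13 of 16 (highest other 13, 5 and 13), and those of 15, 4 and 6 in PBMC in 5, 14 and 13 (highest other 21, 12 and 15). For the difference between cell types the fit without the block called 0 genes for each drug. At least as many were given by 25 of 25 regroupings (highest other 24 for IVM and 2618 for DEC), and what produced the last was not tested. These regroupings also moved libraries across donors and ignored the pairing.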

How the results depend on the processing

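The GC correction, the fit on genes with a GC value alone and the fit on libraries ending in 1 were chosen after seeing the data. The other alternatives were planned, except leaving out a donor from the correlation between the drugs. In the edgeR fit without the block every adjusted p was 0.9998 or more, so counts that stayed at 0 there are no sign of robustness. Of 159 values of gene counts without the block, 157 stayed at 0. The pairing by the replicate number as block moved the other values, to 3 genes for DEC against DMSO and 8 for IVM against DEC in neutrophils. The smaller spread within donors shows the cause. The interaction counts stayed at 0 in 14 of 14 values. Of 159 values of blocked gene counts 126 were within 1.5 times. Most of these 126 were counts that stayed at 0 in comparisons with 0 blocked calls, which is no sign of robustness. In the neutrophil comparisons with blocked calls, more values moved beyond 1.5 times than stayed within it. For IVM against DMSO in neutrophils, no low-count filter gave 2 (CREM and NR4A3). For DEC against DMSO in neutrophils, no low-count filter gave 14, only the compared groups 5 (FCGR3A and SERTAD1 in addition) and the GC correction 13 (3 on the same genes uncorrected), while DESeq2 gave 2, without CDC42EP2. For IVM against DEC in neutrophils, DESeq2 gave 17 (7 shared), no low-count filter 29, an adjusted p threshold of 0.1 13 and the GC correction 37 (11 on the same genes uncorrected), and with only the compared groups PCF11 was lost. In PBMC, DESeq2 gave 1 (PIM1) and no low-count filter 63 for IVM against DMSO, no low-count filter 32 for DEC against DMSO, and no low-count filter 21 and only the compared groups 1 (SERPINB2) for IVM against DEC. The cause was not tested. With labels exchanged within donors, the unfiltered fits called up to 39, 22 and 43 genes in neutrophils and 560, 42 and 119 in PBMC.

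Leaving out a donor or a compared library, blocked counts ranged from 1 to 6 for DEC against DMSO and from 0 to 7 for IVM against DEC in neutrophils, and the others were 0 to 0 (edgeR). For DEC against DMSO CXCL1 was called alone without replicate 1, 2 or 3, without DMSO library 3, and without DEC library 1, 2, 3 or 4. The count was 2 without replicate 4, 4 without replicate 5, 2 without DMSO library 1, 2 or 5 or IVM library 1, 2 or 4, 4 without IVM library 3, 5 without DMSO library 4 and 6 without DEC library 5. For IVM against DEC it was 0 without replicate 1, 1 without replicate 2 or IVM library 2, 5, 3 and 7 without replicates 3, 4 and 5, and 2 without IVM library 1. It was 6, 7 and 7 without IVM libraries 3, 4 and 5, 6, 4, 5, 3 and 5 without DEC libraries 1 to 5, and 21 without DMSO library 4. In PBMC SOCS1 passed for IVM against DMSO without DEC library 4, and SERPINB2 for IVM against DEC without DMSO library 2. Some removals lowered the count and others raised it. Whether the smaller number of samples or the library left out caused this was not tested.

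For lists, the block gave 2, 9 and 1 in neutrophils and 15, 4 and 6 in PBMC (IVM, DEC, IVM against DEC), from 0, 3, 0 and 9, 2, 0 without it. The estimated correlation gave 0 in each, without and with the block, as did fry, except 1 for DEC in neutrophils with the block. Without the block, leaving out a donor gave 0 to 3, 0 to 2 and 0 to 0 lists in neutrophils and 1 to 12, 1 to 3 and 0 to 3 in PBMC. With the block it gave 0 to 6, 2 to 10 and 0 to 8, and 9 to 22, 1 to 9 and 1 to 10. The lowest PBMC counts without the block came without replicate 3 for IVM (1) and DEC (1). The correlation between the drugs' log2 fold changes went to -0.028 in neutrophils and 0.095 in PBMC with the controls split, and ranged from 0.42 to 0.48 and 0.51 to 0.69 with a donor left out. Splitting removes the shared controls and also leaves fewer donors per drug, and these were not told apart.

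For 244 gene results without the block, 1446 of 1458 values stayed uncalled with a log2 fold change within 1 SE. Adjusted p values of that edgeR fit were 0.9998 or more, so staying uncalled is no sign of robustness. Of the others, 11 passed with the block, and MT1G with IVM in PBMC moved, to 0.23 in voom and 0.25 without replicate 4. CXCL5 between the drugs in PBMC went to 0.34 without replicate 5. The sign differed in 10 of the 1458 values and in 34 of 1210 with a donor left out. Of the 11 results called with the block, 52 of 55 values of alternatives passed, and 79 of 165 with a donor or a compared library left out, while 86 did not. None of the called genes changed sign in these alternatives. With depth and spread as here, a 1.2-fold change was recovered in 32% of simulated neutrophil genes and 14% of PBMC genes.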

Other observations

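The GC correction of this part was chosen only after the results were seen, and its counts are not planned tests.

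Interferon-stimulated genes in PBMC stood near 0 with IVM (median log2 fold change -0.02, adjusted p = 0.833) and above 0 with DEC, where 36 of 41 were positive without passing (median 0.15, adjusted p = 0.0983). With the GC correction they passed with DEC (adjusted p = 0.000896, or adjusted p = 0.812 with an estimated correlation), as did neutrophil markers, higher with DEC (median 0.16, adjusted p = 0.0124, or adjusted p = 0.812 with an estimated correlation). Monocyte markers in PBMC had medians of -0.09 with IVM and 0.09 with DEC (adjusted p = 0.700 and 0.310), and were lower with IVM than with DEC among genes with a GC value, before and after the correction (adjusted p = 0.0300 and 0.0247, or adjusted p = 0.952 and 0.898 with an estimated correlation). With the correction 9 lists passed for DEC in PBMC, against 4 before it on the same genes, all 9 at adjusted p = 0.812 with an estimated correlation. Higher beside those named were the chemokine receptor, interferon gamma, cholesterol synthesis, respiratory chain, ribosomal and apoptosis lists, and lower were glycolysis and hypoxia genes. With the correction, 8 of 16 exchanges of labels within donors gave at least 9 lists, the real labels included (highest other 12). This count of lists therefore did not stand apart from exchanged labels.

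With the GC correction and the block, edgeR called 13 genes for DEC against DMSO in neutrophils, and 3 on the same genes without the correction. Lower were CXCL1, DUSP6 and CDC42EP2, the neutrophil chemokine gene CXCL8 (log2 fold change -0.25), CDCP1 (-0.52), FCGR3A (-0.29), VNN3 (-0.18) and MCEMP1 (-0.20). Higher were AMD1 (0.22), SERTAD1 (0.27), G3BP1 (0.24), TIPARP (0.23) and the actin-binding protein gene DBN1 (0.22). Of the 16 exchanges of labels within donors the highest other gave 1 call, too few exchanges for a share under 0.05. For IVM against DEC the correction gave 37 calls, with a highest other of 9, and 11 calls stood on the same genes without it.

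Log2 fold changes in PBMC rose with GC content across genes at 1 CPM or more, which are not independent replicates. Spearman's coefficient was 0.71 for DEC and 0.45 for IVM, and -0.44 between IVM and DEC. For DEC it was 0.26 to 0.67 in single donors and above 0 in 5 of 5, and 0.57 without the donor of replicate 2. For IVM it was -0.17 to 0.69 in single donors and 0.10 without the donor of replicate 2. Genes at an unadjusted p under 0.05 had a median GC content of 60.0% when higher with DEC and 38.5% when lower, against 48.1% for all genes.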
